A study of Homo sapiens with 6 samples.

How the data were processed

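Total RNA of BL2 and BL2 AID-/- cells, 3 samples each, was extracted with Trizol, amplified with an Illumina TotalPrep kit and hybridized as Cy3-streptavidin-labelled product to Illumina whole-genome bead arrays, per the labels' protocols. The deposited non-normalized table holds 1 linear intensity and 1 detection p-value per probe and array, per the file headers. No background had been subtracted from these intensities, since the lowest value on any array was 74.6. The deposited detection p-value of each probe is its standing against the negative controls of the array. Its steps in the values correspond to 770 such controls. The second table deposited by the authors holds processed intensity values whose scale was not stated. Set against the non-normalized table array by array, its values had a rank correlation of 1 with the raw intensities, were linear, and had sorted values that differed by at most 0.0372% between arrays (ranks from 1 to 99%), the mark of quantile normalization. Its column medians were 102.75 to 102.76, and its shared distribution was 1.03 times the mean of the raw arrays. The origin of this factor stays unknown. The scanning software and the array slides are not given in the sources used here. Sample columns were matched by name, and 0 columns belonged to other samples.

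The non-normalized intensities were background corrected by normexp with negative controls inferred from the detection p-values (limma's nec, offset 16), quantile normalized and put on the log2 scale. The offset lifts dim probes, so fold changes of dim genes are understated. A probe was kept if its detection p was under 0.05 on at least 3 of the 6 arrays, which left 17796 of 47323. In the platform annotation 30113 probes had 1 gene symbol, 8 had several and 17202 had none, and only probes with 1 symbol were named. Symbols were updated through their gene numbers to a RefSeq gene table (assembly GRCh38.p14, used for names and gene order only), which held 30074 of these probes. No genome build is named with the data, so coordinates are not given. A gene was represented by its probe with the highest mean, and unnamed probes were tested singly, which gave 14510 features. Probes of a gene did not always go the same way. Of 2610 genes with more than 1 kept probe, 623 had more than 1 probe past the threshold, and in 119 of these they passed in opposite directions. For BCL2L1, CDKN1B, ERAP2, PSMB9, UHRF1 and ZAP70 1 of 2 kept probes passed, for BCL2 2 of 3 and for LCK 3 of 4, and the others went the same way without passing. A dim probe can fall only as far as background, so its log2 difference is limited.

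Differences between lines were tested with lmFit and eBayes of limma version 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. All tests were two-sided, and each SE is that of the moderated fit. Intensities, SDs and n refer to 3 arrays per line. A gene with no probe detected on any array of a line is given as at least N-fold. The bound sets the brighter line's mean log2 value against the dim line's mean of, per array, the higher of the lowest signal of any detected probe and the probe's own signal. Gene lists and the rule for named genes were fixed before the data were examined. So were the tests and the alternatives, except those named below as chosen or changed afterwards. The 28 of 32 lists with at least 5 tested members were compared with all other features by camera with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Some genes, such as CCR7, LTB, CD27, CIITA, CD22 and XBP1, belong to more than 1 list.

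The named genes were, by the rule, the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05 that were detected on all 3 arrays of a line, leaving out provisional symbols. For each list up to 4 members past the threshold with the largest change could be named. A further item of the rule is not reported here.

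The replicate numbers of the lines were checked for pairing by correlating the deviations of same-numbered arrays from their line means, and the outcome is given with the alternatives. The whole procedure was tested on simulated arrays with known changes, drawn from the BL2 means and the spread of each probe for BL2 AID-/- against BL2, with 14781 features tested. It recovered 8 of 46 changes of 1.25-fold, 24 of 45 of 1.5-fold, 28 of 44 of 2-fold and 38 of 42 of 4-fold, and 10 of 108 calls (9.26%) were false, more than the 5% the threshold aims at. The median estimate for a 4-fold change was 3.24-fold. An earlier simulation, with background noise as wide as the spread between dim probes, was replaced after its result was seen. It recovered 0 of 49, 8 of 49, 21 of 46 and 34 of 42 of these changes, and 4 of 67 calls were false. Both simulations changed only a small share of the features, whereas 38.7% of features passed in the data. Their rates of recovery and of false calls therefore do not carry over to the data.

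The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, no filter on detection, a stricter filter (detection p under 0.01 on all arrays of a line), averaged probes, every probe on its own, the authors' processed intensities, eBayes with trend and robust options, array weights, the replicate number as a block, and leaving out each array in turn. For the lists, an estimated correlation and fry were added. Leaving out each array was first run with the filter recomputed on the other arrays. Keeping the filter on all 6 arrays was chosen after that result was seen, and median scaling over detected probes was also chosen after the data were seen. A slide effect was not tested.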

Results

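RNA from BL2, a line of Burkitt lymphoma B cells, was compared with RNA from BL2 AID-/-, a derivative line whose label marks the loss of AID. AID deaminates cytosines in immunoglobulin genes during somatic hypermutation and class switching of B cells. Each line was measured on 3 single-colour Illumina bead arrays with 47323 probes. Between 17171 and 18523 probes were detected on each array, and the number of arrays limits the precision. The labels number the replicates but do not say that they were separate cultures, or how many knockout clones were used, so p-values measure only the spread between these samples, which may be technical. The mean raw intensity was 285 ± 2.67 (SD, n = 3) for BL2 and 343 ± 5.78 (SD, n = 3) for BL2 AID-/-, and every BL2 AID-/- array was brighter than every BL2 array. After normalization, arrays of the same line correlated at 0.995 to 0.996 and arrays of different lines at 0.980 to 0.981. The slide of each array is not given in the sources used here, so a batch that coincides with the lines cannot be told apart from them.

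The comparison asks how the transcripts of BL2 AID-/- cells differ from those of BL2 cells. The loss of AID goes with the line, so its effects cannot be told apart from other differences between the lines, such as clonal ones. The chemokine receptor gene CCR7, which guides lymphocytes into lymphoid tissue, was not detected on any BL2 array and reached a mean log2 intensity of 7.63 ± 0.05 (SD, n = 3) in BL2 AID-/-, at least 7.38-fold higher. The lipid droplet coat gene PLIN2 rose by 2.04 on the log2 scale (SE 0.07) and by 1.10 on its other kept probe, the cohesin subunit gene STAG3 by 2.02 (SE 0.07) and the interferon-regulated transcription factor gene IRF1 by 1.82 (SE 0.08). In the other direction, S100A4, which encodes a calcium-binding protein linked to cell motility, had a mean of 9.66 ± 0.02 (SD, n = 3) in BL2. It was not detected in BL2 AID-/-, at least 30.4-fold lower. SNURF and SNRPN, which share an imprinted locus expressed from the paternal chromosome, were also much lower. SNURF, detected on 2 of the 3 BL2 AID-/- arrays, fell by 4.44 on the log2 scale (SE 0.07), and SNRPN was at least 15.9-fold lower on its brightest probe and not detected in BL2 AID-/- (log2 difference of -2.70 on the dimmest of 3 kept probes). SLFN11, which blocks stressed replication forks, fell by 4.23 (SE 0.09). It was detected on 1 of the 3 BL2 AID-/- arrays, so its signal there is near background and the size of the fall is approximate. The dimmer of its 2 kept probes had -2.30 and was not detected in BL2 AID-/-.

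Further large rises were found for SIPA1, a GTPase activator for Rap proteins, with a log2 difference of 1.89 (SE 0.08) on its brightest probe but 0.14 on the other kept one, which did not pass, and for FNBP1, which encodes a membrane-curving protein of endocytosis, with 1.79 (SE 0.08). ID1, an inhibitor of basic helix-loop-helix transcription factors, rose by 1.73 (SE 0.08) and was detected on 1 of the 3 BL2 arrays. UMODL1 rose by 1.88 (SE 0.10) and ADGRL1, an adhesion receptor gene, by 1.65 (SE 0.08). CCDC85A, NINJ2 and ATL3 were not detected on any BL2 array and were at least 3.73-fold, 3.37-fold and 2.76-fold higher in BL2 AID-/-. Among further falls, ACSS2, which makes acetyl-CoA from acetate, was at least 9.93-fold lower on its brightest probe and RHPN2 at least 8.12-fold lower, both without detection in BL2 AID-/-. The dimmest of the 3 kept ACSS2 probes, with a mean of 4.99 in BL2, had a log2 difference of -0.71. GNPDA1, an enzyme of hexosamine breakdown, fell by 3.51 (SE 0.08) to a signal detected on 1 of the 3 BL2 AID-/- arrays, so the size is approximate. CMTM7 fell by 3.45 (SE 0.08) and the membrane-binding annexin gene ANXA2 was 11.3-fold lower. On their dimmest kept probes the log2 differences were -1.76 and -1.75, with detection on 0 and 1 of the 3 BL2 AID-/- arrays. RAB15, TRIM44 and the stress kinase gene MAPK13 fell, with log2 differences of -3.18 (SE 0.08), -3.16 (SE 0.11) and -3.12 (SE 0.08), and TRIM44 was detected on 2 of the 3 BL2 AID-/- arrays. In limma, the adjusted p of these 24 genes was at most 2.06e-05.

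**Figure D1:**
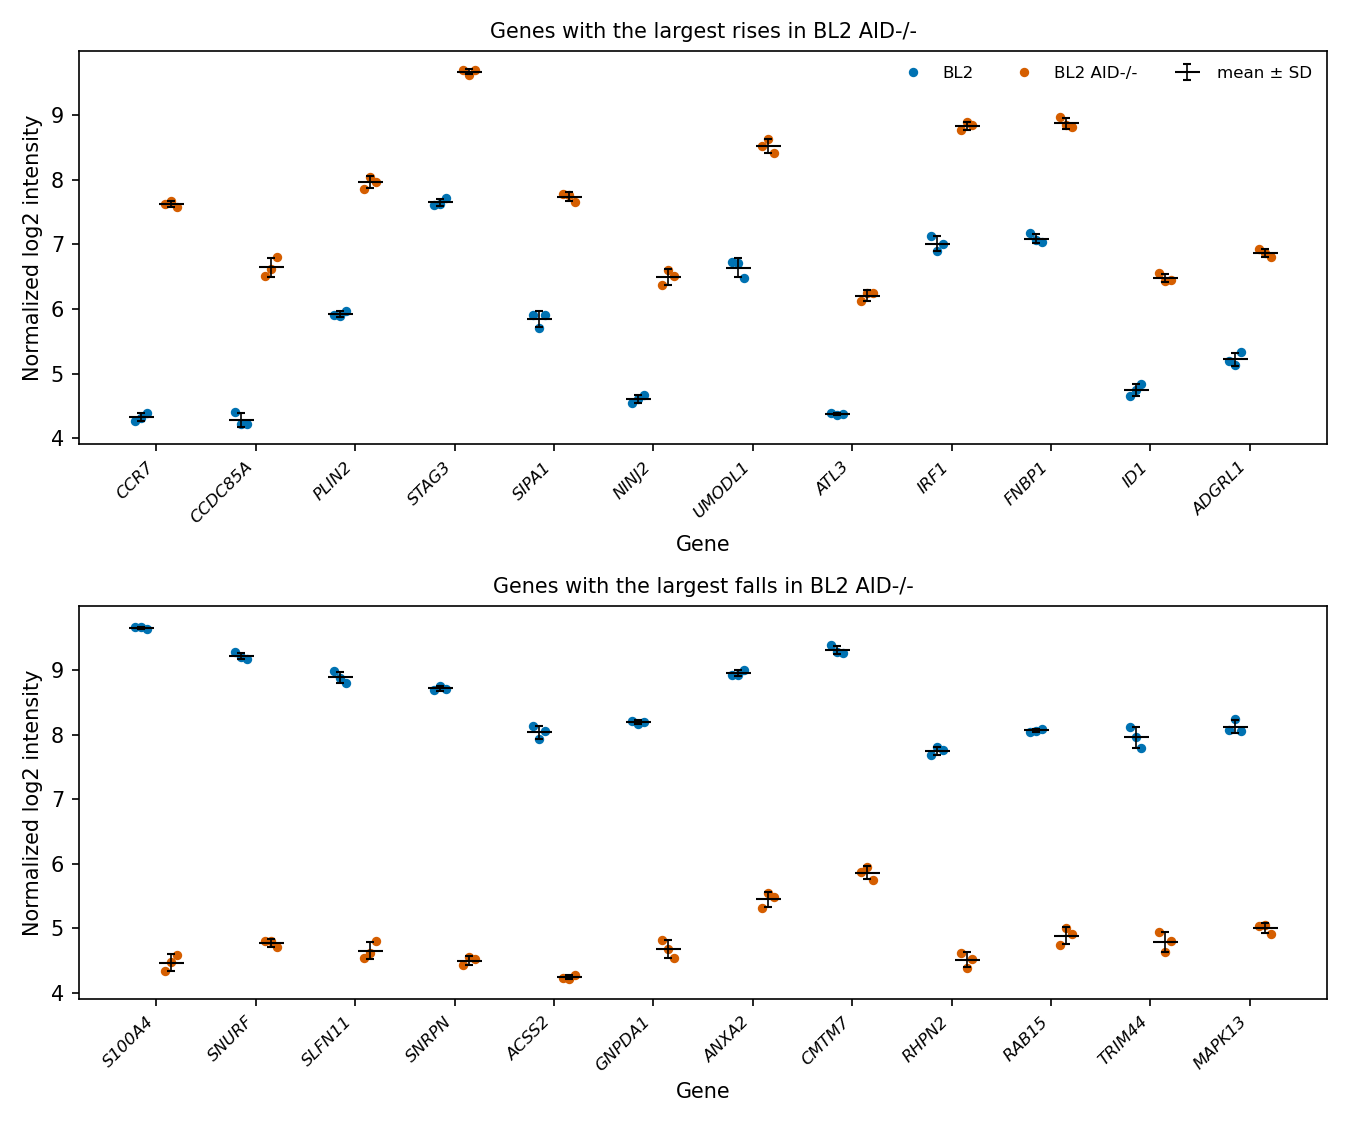
Normalized log2 intensity (vertical axis) of the 12 genes with the largest rises and the 12 with the largest falls in BL2 AID-/-, with points for single arrays (blue for BL2, orange for BL2 AID-/-) and black bars for the mean ± SD of 3 arrays. S100A4 goes from a mean of 9.66 in BL2 to 4.47 in BL2 AID-/-, where it was not detected.

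Of 14510 features tested, 10067 of them genes and 4443 unnamed probes, 3044 were higher and 2571 lower in BL2 AID-/- at an adjusted p under 0.05 in limma. A change of at least 2-fold was found for 112 higher and 175 lower features, of which 87 and 155 were named genes. Most calls were small, with 4113 of 5615 under 1.5-fold. The split between directions depended on the scaling of the arrays. With quantile normalization 54.2% of the calls were higher in BL2 AID-/-, but with arrays scaled to the same median 87.3% were (6714 higher, 974 lower). The median log2 difference of all features then moved from 0.02 to 0.24. That median is taken over all 47323 probes and falls among undetected ones. Median scaling thus aligns background and can leave a brightness difference in expressed genes. Scaling over detected probes, chosen after the data were seen, gave 44.8% higher. With it 10 MHC class I and 16 lipid synthesis genes were lower, as with quantile normalization.

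Genes of antigen presentation by MHC class I, which displays peptides of cytosolic proteins to T cells, fell together. Of 16 members tested, 10 fell, none rose and 6 did not pass. At an unadjusted p under 0.05 in limma 13 were lower and 0 higher, and adjusted over the list alone 12 fell. The peptide transporter genes TAP2 and TAP1 fell by 1.32 (SE 0.06, but -0.52 on a dimmer probe of TAP2) and 0.54 (SE 0.08) on the log2 scale, the peptide-trimming gene ERAP2 by 0.69 (SE 0.09) and the immunoproteasome gene PSMB9 by 0.54 (SE 0.07). The list as a whole was lower than the other genes by camera (adjusted p = 0.000114), but not with an estimated correlation (adjusted p = 0.17 with an estimated correlation). Under median scaling, with its shift of all features, 2 members passed as lower and 1 as higher, TAP1 and PSMB9 no longer passed, and the list stayed lower than the other genes (adjusted p = 0.00544).

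Genes of cholesterol and lipid synthesis also fell together. Of 24 members tested, 16 fell, 1 rose and 7 did not pass, and adjusted over the list alone 18 fell and 2 rose. The mevalonate pathway genes MVD and IDI1 fell by 0.65 (SE 0.10) and 0.56 (SE 0.11), ACAT2, which makes acetoacetyl-CoA, by 0.60 (SE 0.07) and the fatty acid synthase gene FASN by 0.54 (SE 0.06). The camera test called the list lower (adjusted p = 0.000114), and the call was lost with an adjusted p = 0.17 with an estimated correlation. Under median scaling 3 members were lower and 4 higher, IDI1 and FASN no longer passed, and the mean of the list turned from -0.28 to 0.04, although camera still ranked it below the other genes (adjusted p = 0.0445).

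Targets of NF-kB and of B cell activation rose on balance. Of 23 members tested, 10 rose, 3 fell and 10 did not pass (16 higher and 1 lower under median scaling), and adjusted over the list alone 12 rose and 3 fell. Besides CCR7, the lymphotoxin gene LTB rose by 1.17 (SE 0.06), the cytokine gene IL10 by 0.88 (SE 0.07) and the kinase gene MAP3K8 by 0.83 (SE 0.09). Camera called the list higher (adjusted p = 0.0261), but the adjusted p was 0.688 with an estimated correlation and 0.0973 under median scaling. The call also ended without BL2 replicate 1 (adjusted p = 0.0817) and without BL2 replicate 3 (adjusted p = 0.0525). With the detection filter recomputed on the other arrays, leaving out 1 array ended it in 5 of 6 runs (adjusted p 0.0151 to 0.155), with a mean of 0.24 to 0.41.

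No other list passed camera. Among B cell programmes, 7 of 22 germinal centre genes rose and 6 fell (12 and 2 under median scaling), and adjusted over the list alone 8 rose and 6 fell (camera adjusted p = 0.996). The transcription cofactor gene LMO2 rose by 1.32 (SE 0.15) from a signal detected on 1 of the 3 BL2 arrays, so the size is approximate, and the B cell transcription factor gene SPIB fell by 1.33 (SE 0.09). Of 15 plasma cell genes 3 rose and 6 fell (6 and 4 under median scaling), and adjusted over the list alone 5 rose and 7 fell (adjusted p = 0.551). CREB3L2 fell by 1.15 (SE 0.07), and IRF4 and XBP1, which drive plasma cell differentiation, by 0.82 (SE 0.09) and 0.67 (SE 0.06), while the costimulatory receptor gene CD27 rose by 0.89 (SE 0.07). Of 21 B cell receptor signalling genes 7 rose and 4 fell (14 and 3 under median scaling), and adjusted over the list alone 9 rose and 4 fell (adjusted p = 0.736). The kinase gene PRKCB, detected on 2 of the 3 BL2 AID-/- arrays, fell by 1.98 (SE 0.09, with -0.89 on a dimmer probe), the inhibitory receptor gene CD22 by 1.00 (SE 0.13) and the kinase gene LYN by 0.76 (SE 0.07). Among the rises was INPP5D, by 0.54 (SE 0.07). Of 19 B cell identity markers 5 rose and 5 fell (8 and 2 under median scaling), over all features and adjusted over the list alone (adjusted p = 0.736), with a fall of the receptor gene TNFRSF13B by 1.53 (SE 0.07) and a rise of the pre-B cell gene VPREB3 by 1.02 (SE 0.07). Of 4 immunoglobulin-related genes tested, too few for camera, the surrogate light chain gene VPREB1 rose by 1.59 (SE 0.08), VPREB3 rose and IGLL1 fell by 0.31 (SE 0.07), with the same 2 rises and 1 fall adjusted over the list alone. The fall of IGLL1 did not pass under median scaling.

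Of 19 MHC class II genes, whose products present peptides to helper T cells, 8 rose and 2 fell (14 and 0 under median scaling), with the same counts adjusted over the list alone (camera adjusted p = 0.313). HLA-DPB1 rose by 1.00 (SE 0.10), the class II transactivator gene CIITA by 0.82 (SE 0.08) and the lysosomal reductase gene IFI30 by 0.75 (SE 0.09). Of 22 interferon response genes 4 rose and 7 fell (9 and 5 under median scaling), and adjusted over the list alone 5 rose and 7 fell (adjusted p = 0.736). The antiviral GTPase gene MX1 fell by 2.70 (SE 0.14) to a signal detected on 1 of the 3 BL2 AID-/- arrays, so the size is approximate, and IFITM2 by 1.06 (SE 0.11), while its paralog IFITM1 rose by 0.99 (SE 0.08) and the tetherin gene BST2 by 0.94 (SE 0.08). Of 20 homing and adhesion genes 4 rose and 5 fell (11 and 3 under median scaling), with the same counts adjusted over the list alone (adjusted p = 0.996). The adhesion gene CD58 fell by 1.13 (SE 0.09) and the sphingosine phosphate receptor gene S1PR4 by 1.05 (SE 0.11).

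Relatives and partners of AID were examined next. Of 5 APOBEC cytidine deaminase genes tested 3 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.313). APOBEC3B was not detected in BL2 AID-/- and was at least 4.84-fold lower, and APOBEC3G and APOBEC3D fell by 0.72 (SE 0.14) and 0.48 (SE 0.10), the latter not past the threshold under median scaling. APOBEC3F rose by 0.77 (SE 0.09) on its brightest probe, but another of its 4 probes fell, and their average was -0.04. Of 26 AID cofactor and uracil repair genes 5 rose and 3 fell (16 and 2 under median scaling, 2 and 3 under cyclic loess), and adjusted over the list alone 2 rose and 3 fell (adjusted p = 0.912). PRKDC, the catalytic subunit of the DNA end-joining kinase, rose by 1.34 (SE 0.07) on its brightest probe, but the other 3 of its 4 kept probes did not pass, with a lowest value of -0.30. The repair scaffold gene XRCC1 rose by 0.66 (SE 0.07), whereas SUPT5H, an elongation factor gene and AID partner, fell by 0.69 (SE 0.07). Of 32 genes at loci reported as off-target sites of hypermutation 13 rose and 8 fell (22 and 2 under median scaling), with the same counts adjusted over the list alone (adjusted p = 0.736), among them SOCS1 with a rise of 0.85 (SE 0.08). Of 11 genes of DNA methylation and its removal 4 rose and 3 fell (6 and 0 under median scaling, 4 and 4 under cyclic loess), and adjusted over the list alone 4 rose and 4 fell (adjusted p = 0.912). GADD45B rose by 0.67 (SE 0.13) and the maintenance factor gene UHRF1 by 0.33 (SE 0.07). IDH2 had a log2 difference of -0.45 (SE 0.08), a fall that did not pass under median scaling.

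Of 18 double strand break response genes 4 rose and 6 fell (9 and 1 under median scaling), and adjusted over the list alone 5 rose and 6 fell (camera adjusted p = 0.736), with BRCA1 up by 0.63 (SE 0.08) and XRCC2 down by a log2 difference of -0.62 (SE 0.08). Of 20 p53 targets 5 rose and 4 fell (15 and 2 under median scaling), with the same counts adjusted over the list alone (adjusted p = 0.736). The cell cycle inhibitor gene CDKN1A rose by 0.63 (SE 0.10), and TP53I3, not detected in BL2 AID-/-, was at least 1.69-fold lower. ZMAT3 counted as a fall on its brightest probe, with a log2 difference of -0.85. But its other 2 kept probes passed as higher, with 0.43 and 0.41. Of 24 apoptosis regulators 7 rose and 5 fell (16 and 3 under median scaling, 4 and 6 with scaling over detected probes), and adjusted over the list alone 9 rose and 5 fell (adjusted p = 0.736). The survival genes BCL2 and BCL2L1 fell by 0.67 (SE 0.07) and 0.68 (SE 0.08), and the death-promoting gene BIK rose by 0.87 (SE 0.08). Of 31 cell cycle genes 7 rose and 5 fell (22 and 2 under median scaling), with the same counts adjusted over the list alone (adjusted p = 0.912), with BIRC5 up by 0.65 (SE 0.08) and the inhibitor gene CDKN1B down by a log2 difference of -0.58 (SE 0.10). Of 29 MYC targets 4 rose and 8 fell (16 and 1 under median scaling), with the same counts adjusted over the list alone (camera adjusted p = 0.736). NOP56 had a log2 difference of -0.58 (SE 0.07) on its brightest probe, but its other kept probes, at 0.33 and 0.15, did not pass. PHB1 rose by 0.57 (SE 0.07) and the nucleolar gene FBL by 0.55 (SE 0.09). Of 7 replication-dependent histone genes 1 rose (H2AC20, 0.36, SE 0.11) and 1 fell (H1-2, -0.61, SE 0.19), with the same counts adjusted over the list alone (adjusted p = 0.912) but 4 higher and 0 lower under median scaling. H1-2 did not pass under median scaling, and neither gene passed without the filter on detection.

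Stress and metabolic lists moved in both directions. Of 20 unfolded protein response genes 2 rose and 4 fell (12 and 1 under median scaling), with the same counts adjusted over the list alone (camera adjusted p = 0.736), with a rise of CRELD2 by 0.68 (SE 0.06) beside the fall of XBP1. Of 21 genes of the ATF4 amino acid response 8 rose and 5 fell (14 and 1 under median scaling), and adjusted over the list alone 9 rose and 5 fell (adjusted p = 0.736). The serine synthesis gene PSAT1 fell by 0.78 (SE 0.08) and the glycine transporter gene SLC6A9 rose by 0.78 (SE 0.14). Of 29 hypoxia and glycolysis genes 7 rose and 6 fell (19 and 2 under median scaling, 5 and 6 under cyclic loess), and adjusted over the list alone 8 rose and 6 fell (adjusted p = 0.912). The vasoactive peptide gene ADM fell by 1.00 (SE 0.07) and the glucose transporter gene SLC2A3 rose by 0.87 (SE 0.08). Of 33 oxidative phosphorylation genes 7 rose and 11 fell, and adjusted over the list alone 9 rose and 11 fell (adjusted p = 0.736), with a fall of the complex I gene NDUFV2 by 0.90 (SE 0.07). Under median scaling 21 of them were higher and 1 lower. Of 15 heat shock protein genes 3 rose and 3 fell (8 and 0 under median scaling, 3 and 5 over detected probes), with the same counts adjusted over the list alone (adjusted p = 0.736). HSPB1 rose by 0.40 (SE 0.07), and HSPD1 fell by 0.46 (SE 0.06), with 2 of its 4 kept probes past the threshold (range -1.04 to 0.08), a fall that did not pass under median scaling.

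Reference and control lists were measured in the same way. Of 19 housekeeping genes 4 rose and 2 fell, and adjusted over the list alone 6 rose and 3 fell (camera adjusted p = 0.736), with a median log2 difference of 0.06 that became 0.40, with 15 higher, under median scaling. Of 35 ribosomal protein genes 4 rose and 1 fell in limma, 7 and 2 at an unadjusted p under 0.05, and 0 and 0 adjusted over the list alone (adjusted p = 0.736). Their median of 0.02 became 0.29 under median scaling, where 22 were higher and 0 lower, and -0.03 under cyclic loess, where 1 was higher and 5 lower. RPL13, with 0.40 (SE 0.08), differed the most. Of 31 cancer-testis genes on the array 2 were tested, of which LAGE3 rose by 0.63 (SE 0.07) and TDRD1 fell by 0.84 (SE 0.11), as they did adjusted over the list alone.

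Markers of other cell types were mostly below the detection filter. Of 24 T and NK cell markers on the array 4 were tested, and LCK and CD247 rose by 0.54 (SE 0.11) and 0.39 (SE 0.08). ZAP70 fell by 0.22 (SE 0.07), but was 0.09 higher, without passing, under median scaling. Of 19 myeloid markers 6 were tested, of which 3 rose and 1 fell (camera adjusted p = 0.736). AIF1, a gene of macrophages, rose by 1.65 (SE 0.09), CD68 by 0.64 (SE 0.11), although its other kept probe was at 0.02, and the Fc receptor gene FCGR3A, detected on 2 of the 3 BL2 AID-/- arrays, fell by 0.67 (SE 0.10). Of 19 epithelial and fibroblast markers 2 were tested. TAGLN, detected on 2 of the 3 BL2 arrays, rose by 0.57 (SE 0.14), and KRT19, not detected in BL2 AID-/-, was at least 1.26-fold lower. The counts of these 3 lists were the same adjusted over the list alone.

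**Figure D2:**
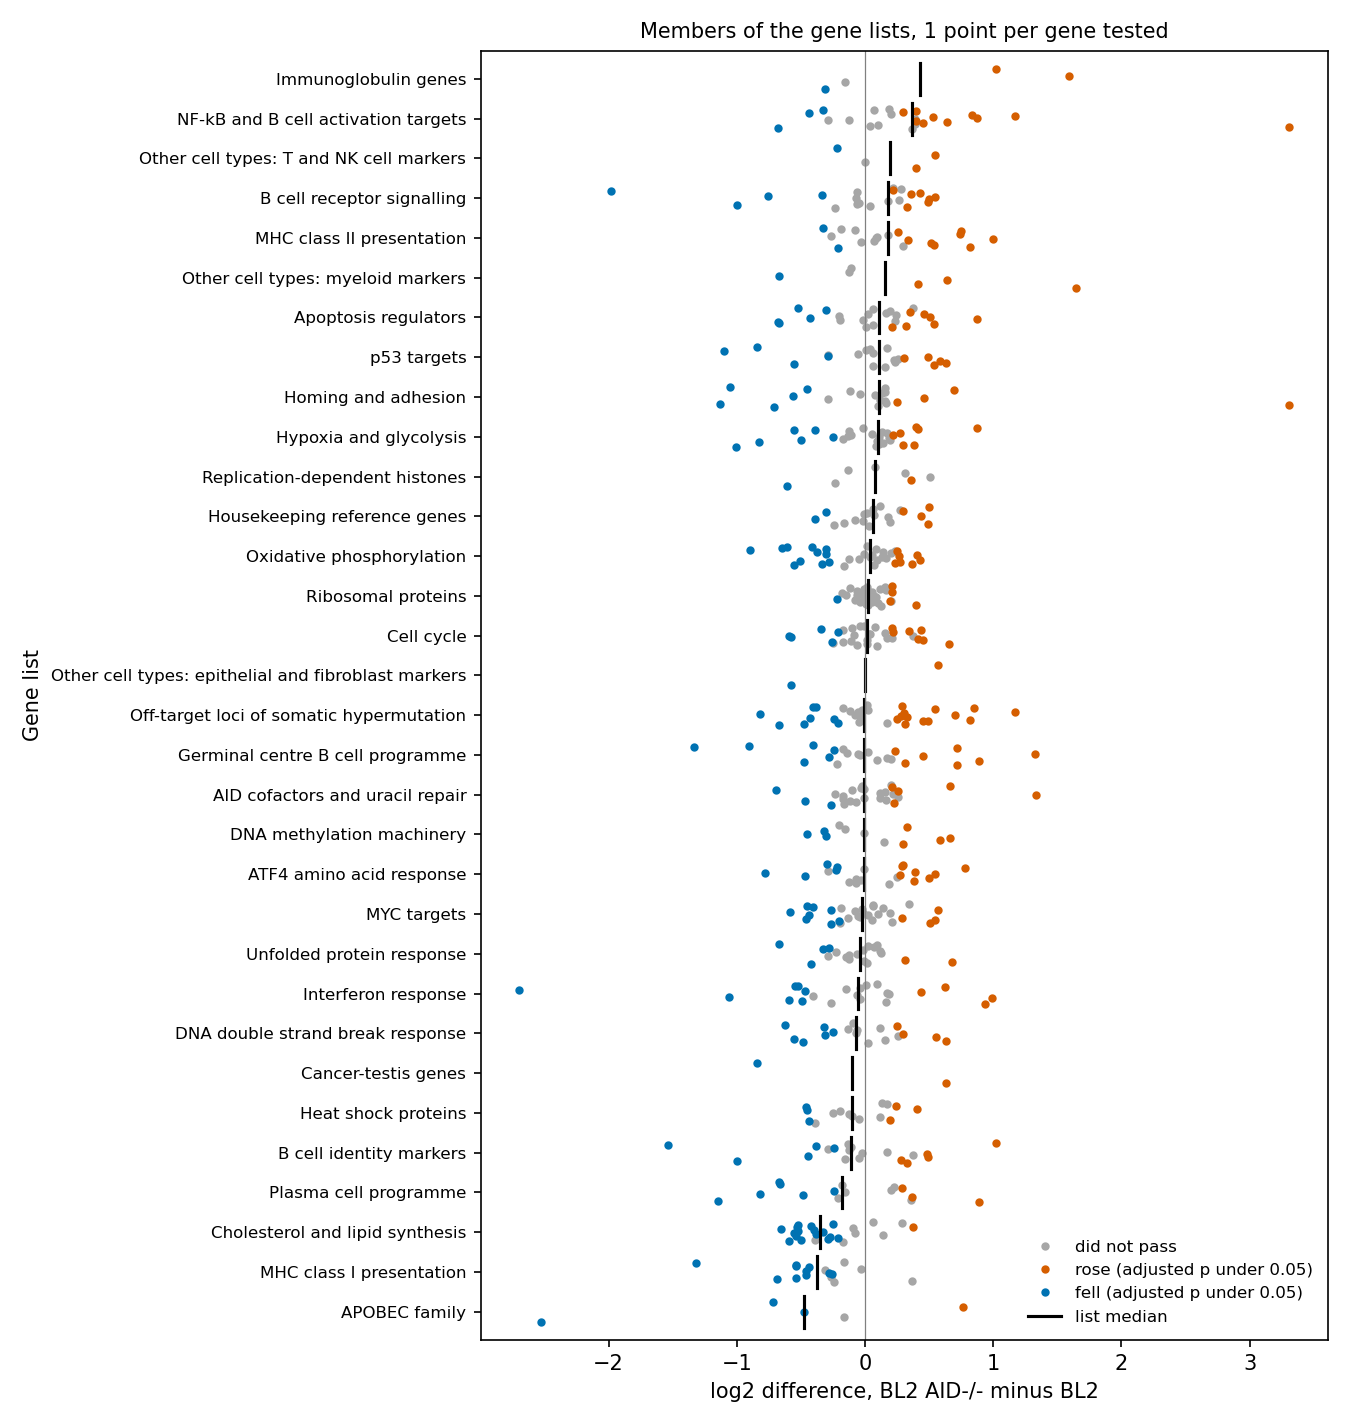
Log2 difference between BL2 AID-/- and BL2 (horizontal axis) for each tested member of the 32 gene lists (vertical axis, ordered by median), with orange points for genes that rose, blue for genes that fell, grey for genes that did not pass and black bars for list medians. The medians of MHC class I presentation (-0.37) and cholesterol and lipid synthesis (-0.35) lie to the left and that of NF-kB and B cell activation targets (0.37) to the right; under median scaling they become -0.10, -0.02 and 0.60.

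None of the 28 lists with a camera test passed with an estimated correlation, where 0 had an adjusted p under 0.05 in place of 3. The estimate was -0.027 for MHC class I, 0.0128 for lipid synthesis and 0.0619 for NF-kB targets, against the preset 0.01. A stronger correlation between genes therefore does not account for the lost MHC class I call, and hardly for that of lipid synthesis. The MHC class I list went from an unadjusted camera p of 5.37e-06 to 0.00816 at this lower correlation. Only with an estimated correlation does camera let the small number of arrays limit its p-values. With the preset one, used in all other camera runs, the p-values do not carry this limit. How much of the loss this explains was not tested. For some lists the median, the mean and the camera direction differed in sign. The median was 0.18 and the mean -0.03 for B cell receptor signalling, which camera ranked upward, and 0.04 and -0.06 for oxidative phosphorylation, ranked downward. Medians of -0.01 stood beside means of 0.05 for AID cofactors and for DNA methylation, 0.06 for the ATF4 response and 0.04 for the germinal centre list, which camera ranked upward except the last. For the off-target loci the median was -0.005 and the mean 0.09, ranked upward.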

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

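Median scaling over detected probes, and the filter kept on all 6 arrays when 1 was left out, were chosen after results were seen; the other alternatives were planned. All 287 features with a change of at least 2-fold kept their direction and passed in every alternative that tested all of them. With the recomputed filter 252 to 274 were tested and at most 1 of these lost its call. Background handling changed the size of folds more than their direction. Without background correction 25 features were at least 2-fold higher and 50 lower, with an offset of 50 it was 45 and 86 and with the authors' processed values 29 and 54. Median scaling gave 6714 higher and 974 lower features, 407 and 98 of them at least 2-fold. Scaled over detected probes, 44.8% of calls were higher (2776 of 6201). Counts under the other alternatives stayed within 1.5 times. Leaving out single arrays gave 2337 to 2647 higher and 2057 to 2172 lower features with the filter recomputed (99 to 128 and 143 to 175 at least 2-fold), and 2425 to 2606 and 2049 to 2173 with it kept (111 to 128 and 172 to 183).

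Of the 3 lists called by camera, 0 passed with an estimated correlation (mean log2 difference 0.38 for NF-kB targets, adjusted p = 0.688; -0.39 for MHC class I and -0.28 for lipid synthesis, both 0.17). Fry included, each of the latter passed in 26 of 27 alternatives (adjusted p 2.09e-08 and 2.74e-08 to 0.17). The NF-kB list passed in 18 (0.000745, by fry, to 0.688). With averaged probes 5 lists passed, adding APOBEC (-0.80, adjusted p = 0.0254) and MHC class II (0.27, 0.0348), the latter also without the filter (0.23, 0.0255). The NF-kB call ended under median scaling (0.62). Its mean ranged from 0.36 to 0.42 over the left-out arrays, with an adjusted p of 0.00731 to 0.0817. It ranged from 0.237 to 0.411 with the filter recomputed (0.257 without BL2 AID-/- replicate 3), where 5 of 6 runs ended the call (adjusted p 0.0151 to 0.155) and CCR7 dropped out of the list whenever a BL2 AID-/- array was left out. The recomputed filter was run first, and the kept one after this was seen. By fry, which tests a list's genes on their own, 17 passed: besides the 3, APOBEC (-0.62), MHC class II (0.24), plasma cell (-0.15), AID cofactors (0.0535), MYC targets (-0.0230), cell cycle (0.0296), off-target loci (0.0880), ATF4 (0.0615), oxidative phosphorylation (-0.0645), apoptosis (0.0664), adhesion (0.0713), ribosomal proteins (0.0435), housekeeping (0.0771) and myeloid markers (0.30).

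Of 138 single genes followed through the alternatives, 107 never lost their call or direction where tested. Here too, every probe on its own meant the brightest probe of each gene. CCR7, S100A4 and 10 others were left out by the recomputed filter in at least 1 run, and the stricter filter left 136. With averaged probes APOBEC3F turned to -0.0361, and under median scaling PDIA6 turned to 0.0256 and ZAP70 to 0.0896, all without passing. The replicate block gave 2705 higher and 2290 lower features. Deviations of same-numbered arrays correlated at 0.02, -0.01 and 0.01, so the numbers do not pair the samples. No slide block was run, since none is given. In the other splits into 3 and 3 arrays, limma called 0 features (233 to 312 at an unadjusted p under 0.05, against 6892). These mix the lines, so the line difference counts as spread and fixes a low count, which leaves chance untested. Of 10 splits only the real one gave as many as 3044, 2571, 112 or 175, the lowest possible share (0.1). A curve on mean signal explained 6.32% of the variance of fold changes under median scaling. That argues against a trend with signal as the main source of the spread of fold changes over all features. The curve cannot show a shift shared by all features, such as the median of 0.24 under this scaling. Nor does it single out the 2-fold changes, so it draws no line between these and array brightness. This test was planned for quantile-normalized values and moved to median-scaled ones afterwards, since quantile normalization removes such a curve.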

Other observations

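Several abundant RNAs that are not messengers were lower in BL2 AID-/-, a group chosen after its values were seen. RNA28SN5, a ribosomal RNA gene, fell by 2.26 on the log2 scale (SE 0.08) and RNA18SN5 by 0.83 (SE 0.06). The U3 genes SNORD3C and SNORD3D, whose RNA guides ribosomal RNA processing, fell, with differences of -2.30 (SE 0.07) and -2.18 (SE 0.09), and the spliceosomal RNA gene RNU1-1 was 2.38-fold lower. RNY3 fell by 0.66 (SE 0.08) and RN7SK, a regulator of transcription elongation, by 0.38 (SE 0.07). RN7SL1, the RNA of the signal recognition particle, had a difference of 0.03 (SE 0.08), close to the top of the signal range. Small Cajal body RNAs (9 tested, median 0.10, 1 higher and 2 lower) and RPPH1 (0.24, SE 0.11, adjusted p = 0.134), also outside the group, did not share the fall. Of 22 ribosomal, U-type, U3, 7SK and Y RNAs tested 18 were lower in limma and 0 higher, also at 0 higher under every scaling, with 16 lower under median scaling.

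The tests on the noncoding RNAs, on SNRPN and SNURF and on gene length were chosen only after the results were seen. Lower carry-over of all RNA without a poly(A) tail would lower the other snoRNAs too, if their probes measure RNA without a tail. Whether they do was not examined. The 84 other snoRNAs detected on all 6 arrays had a median log2 difference of 0.0696, with 8 higher and 8 lower. The 22 RNAs of the group above, not all of which passed, had a median of -0.94. All 113 other snoRNAs tested had a median of 0.06, with 8 higher and 9 lower. Under median scaling 39 of the 84 snoRNAs were higher and 0 lower (0.28 against -0.59), and over detected probes 7 were higher and 13 lower (-0.03 against -0.90). Since it is not known what these probes measure, the values do not decide about a uniform loss of RNA without a tail. They show only that the probes of the other snoRNAs did not share the fall. A single outlying array is argued against by the fall in each array. Set against the mean of the other line, the 6 medians over the 22 RNAs of the group lay between -0.99 and -0.82. A difference in RNA quality, in a labelling batch or in the lines themselves was not tested, and each could still account for the fall.

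SNRPN and SNURF have 6 probes, of which 4 were kept. All 4 fell, with a smallest log2 difference of -2.70, which argues against a fault of 1 probe, although the genes share a transcript. A net loss of a larger chromosome region would lower neighbours that are expressed from both chromosomes. But the 10 nearest tested genes had a median of 0.0404, and in limma 0 of them were lower and 1, TUBGCP5, was higher (0.33, adjusted p = 0.0213). UBE3A had a difference of 0.03 (SE 0.09). MAGEL2, a paternally expressed neighbour singled out after its value was seen, was at 0.24 (SE 0.09, adjusted p = 0.0737), so it does not share the fall. Whether the signals of MAGEL2 and the other neighbours left room for a fall was not examined, which limits what they say about a loss. A loss or a silencing limited to the locus, or a change between clones, may each explain the fall and were not tested. Neighbours expressed from both chromosomes cannot show a change of the paternal copy that keeps the copy number, so such a change of a larger region was not tested either.

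Genes next to each other on a chromosome had slightly similar changes. Across 10049 genes, which are not independent replicates, the rank correlation of adjacent genes was 0.0591, above the highest of 1000 shuffles of gene order (0.0291). Without pairs that share the first 3 letters of their symbol it was 0.0559 (highest shuffle 0.0313), which argues against gene families as the source, and after a trend on gene length was removed it was 0.0503. A copy number difference between the lines could give such a pattern, and so could shared regulation of neighbours. The correlation was 0.055 at 10 places apart, about as high as for adjacent genes, and 0.0177 at 20. The similarity is thus not limited to adjacent genes. It is low over all genes, which does not limit the size of a change in a single region.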
